A study of Mus musculus with 16 samples.

How the data were processed

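The samples were mouse leukemia cells, with bone marrow as the tissue and C57BL/6 as the strain per the labels, from WT and YBX1-/- animals. They were analysed by SLAM-seq, in which RNA made in the presence of 4-thiouridine (4sU) is recognised afterwards by T-to-C changes in the sequencing reads. Per the labels' protocols, cells were labelled with 50 µM 4sU for 24 h, washed, and chased in medium with 10 mM uridine. A fall of the rate in the chase can come from decay of labelled transcripts or from dilution by new unlabelled ones. These were not told apart, so decay rate and half-life refer to the label in the text below. RNA was collected with TRIzol at 0, 0.5, 1, 3, 6, 12, 18 and 24 h of the chase, and libraries were made from polyA RNA with a NEBNext kit. There were 16 libraries, 1 for each genotype and time point.

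The deposited table held 86993 intervals, 74385 of them with different coordinates, for 21177 genes; 21148 gene identifiers were matched to a symbol. Each interval had a T-to-C rate per library, which the authors deposited as a fraction from 0 to 1. Whether the denominator of the fraction was reads or covered T positions, and which program counted the conversions, is not given in the sources used here. In 35467 intervals with a mean coverage above 100, the smallest rate above 0 multiplied by the mean coverage on Ts had a median of 22.46. The coverage is a mean over the libraries, so this value does not give the step of the rate or settle its denominator. The deposited table also gave mean CPM (reads scaled to library size), a coverage signal on Ts and the T content of each interval, as the authors' means over the libraries per the file headers. CASAVA and HISAT2 2.1.0 were named in the submitters' processing notes, together with the human build GRCh38, although identifiers and samples were mouse. Of the different intervals, 99.5% overlapped a UTR of their own gene in the GENCODE annotation of the mouse build GRCm38, and coordinates are given in that build, counted from 1. No depth per library was in the table, so the depth behind a rate is unknown and no interval was given for it. An exact 0 could mean no reads or no converted reads. No unlabelled library was among the samples, so the background of T-to-C changes was not subtracted.

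For each gene with more than 1 interval (13470 genes), the interval with the highest mean CPM was used, a choice made after the table was seen. Rates were put on a percent scale and analysed as log2(rate + 0.1 percentage points). A gene was tested where its rate was above 0 in at least 12 of the 16 libraries, which left 7411 genes. The added 0.1 percentage points shrink log2 differences of genes with rates near 0. A rate of exactly 0 set against a rate above 0 can still give a large difference, whose size depends on the added value.

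The library median was compared between genotypes with a two-sided exact permutation test that exchanged the genotype labels within time points (256 exchanges, smallest possible p 0.0078125). Loss of label per gene was fitted with limma 3.58.1 in R 4.3.3, with a trend, as a straight line over hours in each genotype, and the half-life was minus 1 divided by the slope. The decay rate difference (YBX1-/- minus WT, log2 per h) was the interaction of genotype and hours in a limma model with the time point as a factor, on values from which the library median had been subtracted; it had 6 residual degrees of freedom. A positive difference means slower loss of label in YBX1-/-. The labelling level difference was the genotype term over all time points on the same values. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Gene lists were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation; 19 of 25 lists had at least 5 tested genes. These tests, the lists, the filter and the alternatives were chosen before the data were examined unless stated otherwise. A test on conversions over covered Ts was planned for a table with coverage per library and was not run.

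Genes named in the text followed a rule: Ybx1, Myc and Bcl2 always; for each genotype comparison the largest coefficients in each direction among genes past the threshold with a mean rate above the median, filled up to 5 per direction by smallest p and then said not to pass; the 5 shortest and 5 longest half-lives in WT among genes past the threshold; and up to 4 members with the smallest p for a list. Predicted genes, Rik clones and pseudogenes were left out. Half-lives were also fitted as an exponential with a constant floor (scipy 1.17.1), with the range over fits that left out each time point in turn as their error.

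On simulated data made from the 7411 genes and their own residual spread, the decay difference test recovered 43 of 100 genes with a difference of 0.2 log2 per h and 77 of 100 with 0.4, with 4 false calls. The level test recovered 56 of 100 genes with a difference of 2 and 82 of 100 with 4, with 7 false calls. The simulated noise was independent between genes, while a real library can shift many genes together. The false calls in these data may therefore be more than the simulation shows. The sizes and the source of the spread were set after a first version, with smaller differences and the residuals of straight lines, had recovered few genes. Alternatives covered the pseudocount, the filter, the time window, each time point left out, the centring, the trend of limma, the correlation in camera, the library mean, and the form of the decay curve. The lists of erythroid, lymphoid, megakaryocyte and stromal markers had 4, 4, 3 and 2 tested genes and were not tested. No member of the list of mitochondrially encoded genes was found, and the list of the study's targets, Myc and Bcl2, had 1 tested gene.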

Results

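Label retained by transcripts was followed over a 24 h chase in leukemia cells of 2 genotypes, WT and YBX1-/-. YBX1 is an RNA-binding protein, and the series title places the study's question in its effect on the stability of mRNA in myeloid leukemia cells. There were 8 time points and 1 library for each genotype and time point, with no replicate at any of them. Each comparison therefore uses the time points of what the labels do not describe as separate cultures, and its p-values measure the scatter between time points, not between animals. The depth per library is unknown.

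The targeted gene, Ybx1, carried label in both genotypes, and its rate fell over the chase. Its interval (ENSMUSG00000028639, chromosome 4, 119277981 to 119278367, 3' UTR past the last coding base) had rates in WT of 55.2%, 61.4%, 56.8%, 50.1%, 38.9%, 15.5%, 7.3% and 5.1% from 0 to 24 h. In YBX1-/- the rates were 72.0%, 51.7%, 43.4%, 48.9%, 31.1%, 20.8%, 4.7% and 3.1%. The rate is a share, of reads or of covered T positions, and does not measure the amount of a transcript, so it does not check the genotype. The position of the deletion is not given in the sources used here.

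Most transcripts lost their label within 1 day in both genotypes, and the typical transcript carried less label in YBX1-/-. The median rate of tested genes in WT was 42.9% at 0 h, 49.2% at 0.5 h, 43.6% at 1 h, 19.9% at 3 h, 10.2% at 6 h and 0.847% at 24 h. In YBX1-/- it was 33.3%, 36.7%, 29.8%, 18.2%, 4.76% and 0.768% at the same times. YBX1-/- was lower at 7 of 8 time points, by a mean of -0.35 log2 (SD 0.37, n = 8 time points; two-sided exact permutation p = 0.03125). With the time point 0, 0.5, 1, 6 or 12 h left out, this p was 0.0625, above the threshold. The median slope was -0.26 log2 per h in WT and -0.24 in YBX1-/-, a difference of 0.02 (exact permutation p = 0.102, n = 8), and its direction turned over shorter windows: -0.005 over 0 to 12 h and -0.095 over 0 to 6 h. The YBX1-/- 0 h library stood apart, with a mean correlation across genes of 0.279 with the other libraries of 0 to 1 h, against 0.551 for the WT 0 h library. Genes are not independent replicates. In the YBX1-/- 0 h library 3.64% of tested genes had a rate of 0, against 0.0945% in the WT 0 h library. The SD across genes was 1.71 log2 against 0.65. A low depth of the YBX1-/- 0 h library is not excluded, since its depth is unknown.

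**Figure D1:**
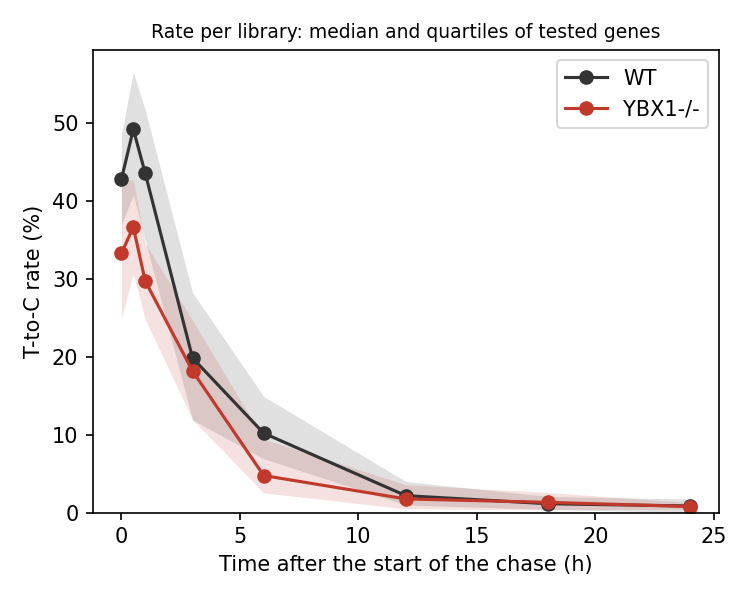
Median T-to-C rate in percent (points and lines) and quartiles (shading) over the tested genes of each library, against hours of chase, in WT (grey) and YBX1-/- (red). The median fell from 42.9% to 0.847% in WT and from 33.3% to 0.768% in YBX1-/-.

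The list medians of ribosomal proteins, respiratory chain subunits, glycolysis and myeloid maturation genes had the longest fitted half-lives in WT cells, which these fits did not compare with other genes by a test. Fits with a constant floor gave 7.2 h for ribosomal proteins (range 6.72 to 7.59 with each time point left out), 5.1 h for oxidative phosphorylation (4.56 to 5.43), 4.48 h for glycolysis (3.52 to 4.94) and 3.95 h for myeloid maturation (3.27 to 4.56). Immediate-early and other short-lived regulators had 1.96 h (1.34 to 2.48), zinc finger genes 1.9 h (1.23 to 2.61) and the tested genes together 2.76 h (2.01 to 3.11). In YBX1-/- the same lists had 6.86 h (6.51 to 7.19), 5.97 h (5.61 to 6.39), 5.35 h (4.96 to 5.76), 5.43 h (5.05 to 5.92), 1.41 h (0.984 to 1.51), 2.02 h (1.32 to 2.28) and 2.66 h (2.11 to 3.17). The genotypes were not compared by a test in these fits.

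Label fell in 7016 of 7411 genes in WT and in 6860 in YBX1-/- (limma, adjusted p under the threshold), and rose in 2 and 0. The median log-linear half-life of these genes was 3.66 h in WT (quartiles 3.0 and 4.24 h) and 3.98 h in YBX1-/- (3.44 and 4.54 h). Across genes the slopes of the genotypes had a Pearson r of 0.312 and a Spearman rho of 0.252. Among the genes whose label fell in WT past the threshold, the shortest half-lives were those of Pecr (2.12 h), Hacd1 (2.13 h), Armcx3 (2.13 h), Dnph1 (2.13 h) and Arg1 (2.16 h), each with a rate listed at 0 from 12 h on. These half-lives depend on the value added to those zeros and do not show the fastest loss. At 6 h in WT Pecr had 30.0% and Hacd1 20.6%, above the library median of 10.2%. Armcx3 (9.1%), Dnph1 (7.1%) and Arg1 (7.7%) lay below it. The longest half-lives among the genes whose label fell in WT past the threshold were those of Sharpin (23.4 h), Babam1 (19.8 h), Lxn (18.8 h), Chil3 (17.9 h) and Ccdc124 (16.5 h). Of these 5, Sharpin, Lxn, Babam1 and Ccdc124 had higher rates at 24 h than at 18 h in WT, so a straight line does not describe them.

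On the uncentred WT slopes, camera with the preset correlation called 6 lists, but for most of them its direction ran against the list median. Camera compares t statistics, which divide a slope by its standard error, and not the slopes themselves. A list with little scatter can therefore be called as falling more without a steeper median slope. Oxidative phosphorylation was called as falling more (adjusted p = 9.91e-10) although its median slope of -0.22 log2 per h was shallower than the -0.27 of the tested genes. The same held for myeloid maturation (adjusted p = 0.0173; median -0.21), splicing factors (0.00517; -0.25) and the proteasome (0.0173; -0.26). Zinc finger genes were called as falling less (5.51e-05) although their median of -0.28 was steeper, and G2/M genes were called as falling less (0.00517; -0.25). None passed with an estimated correlation (adjusted p = 0.924 or more). With the library median subtracted, an alternative chosen after seeing the data, ribosomal proteins (adjusted p = 1.27e-11), oxidative phosphorylation (1.65e-06) and myeloid maturation (2.64e-06) lost label more slowly than other genes and RNA decay factors (0.0268) faster. With an estimated correlation these had adjusted p = 0.545, 0.986, 0.545 and 0.133.

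**Figure D2:**
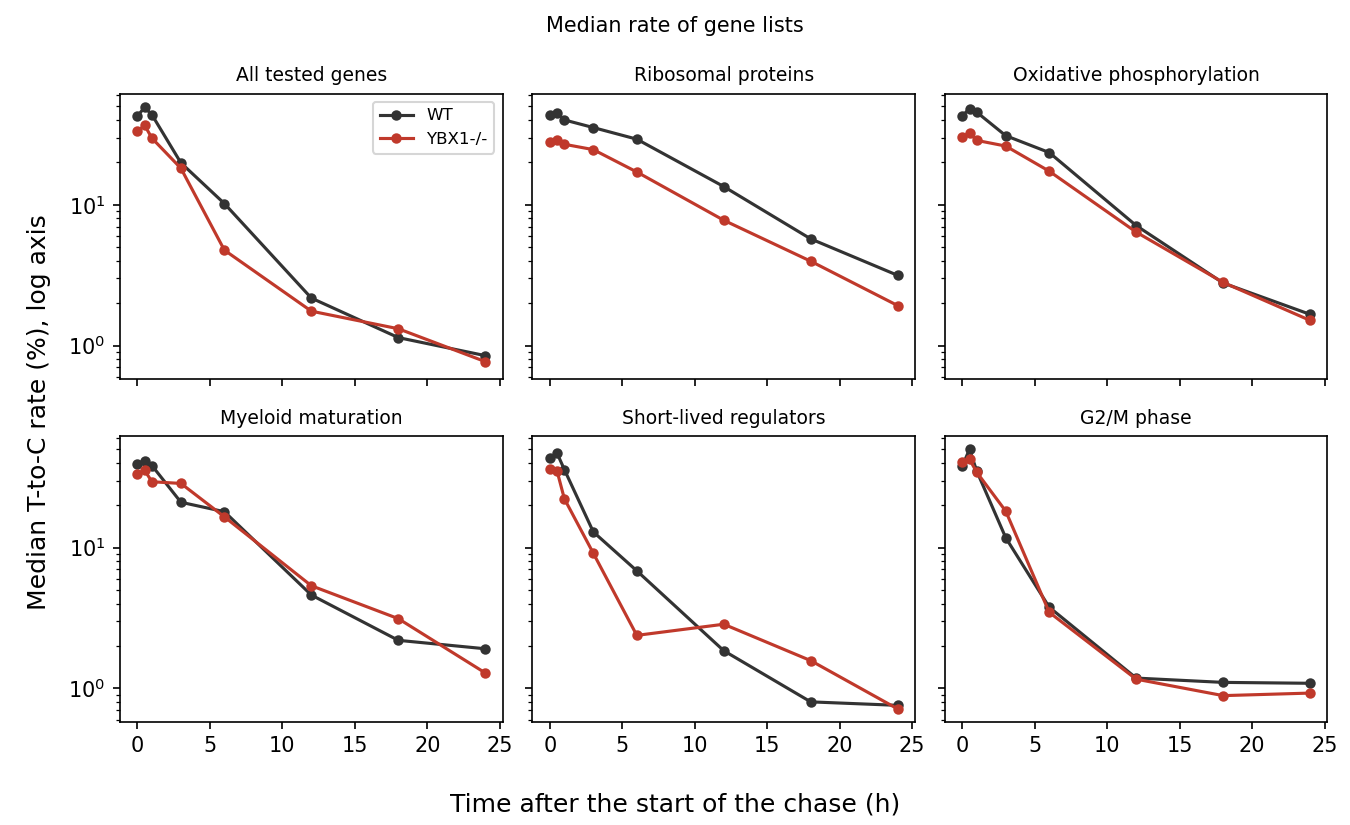
Median T-to-C rate in percent (log axis, values under 0.1 drawn at 0.1) of gene lists against hours of chase, in WT (grey) and YBX1-/- (red). The ribosomal protein list had a fitted half-life of 7.2 h in WT and the short-lived regulators 1.96 h.

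The decay rate differed between the genotypes in 8 of 7411 genes, 3 with slower and 5 with faster loss of label in YBX1-/-. Nptn, which encodes the cell adhesion protein neuroplastin, had 0.7% at 18 h and 0% at 24 h in WT against 11.5% and 1.43% in YBX1-/- (difference 0.17 log2 per h, SE 0.017, adjusted p = 0.0173). Mthfd1l, an enzyme of mitochondrial folate metabolism, had a difference of 0.16 (SE 0.021, adjusted p = 0.0462). Zfp330, a zinc finger gene, had -0.20 (SE 0.015, adjusted p = 0.00455), and Babam1, a member of a complex that acts in DNA repair, had -0.22 (SE 0.028, adjusted p = 0.0462). Ccdc124 had -0.20 (SE 0.026) and Stambpl1, a deubiquitinase, -0.35 (SE 0.047), both with adjusted p = 0.0462. Zfp330 lay on chromosome 8 from 82763621 to 82764228, Babam1 from 71404399 to 71404619 and Ccdc124 from 70868227 to 70868440 on the same chromosome, all in 3' UTRs. In WT their rates did not approach 0: at 24 h they were 14.1%, 26.9% and 22.6%, against 0.344%, 0.463% and 0.577% in YBX1-/-. Fits with a constant floor gave half-lives in WT and YBX1-/- of 1.66 h (1.18 to 2.18 with each time point left out) and 1.74 h (1.46 to 1.8) for Zfp330, 4.61 h (3.23 to 11.9) and 4.62 h (0.724 to 5.48) for Babam1, and 3.95 h (3.24 to 5.59) and 4.15 h (3.62 to 4.75) for Ccdc124, with floors in WT of 16.6%, 21.6% and 16.9%. The same fits gave 3.45 h (3.08 to 3.73) and 5.47 h (4.28 to 6.06) for Nptn and 4.54 h (3.08 to 5.42) and 4.93 h (3.37 to 5.91) for Mthfd1l, so that the ranges of Mthfd1l overlapped. For Stambpl1 they gave 1.84 h (1.32 to 2.17) and 2.31 h (1.44 to 2.74), no longer faster in YBX1-/-, with a floor in WT of 8.17%. Without the genes of chromosome 8, an alternative chosen after seeing the data, 1 gene, Nptn, passed. Nptn itself did not pass in 13 of 20 alternatives, among them pseudocounts of 0.01 (difference 0.26) and 0.5 (0.10), and Zfp330 did not in 6 of 20.

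Slc7a7 (0.23, SE 0.03) and the predicted gene Gm45713 (-0.13, SE 0.017), both with adjusted p = 0.0462, also passed but fell outside the rule for named genes. Xrn1, the main cytoplasmic 5'-to-3' exonuclease, had 0.30 (SE 0.043, adjusted p = 0.0538) and did not pass, nor did Dnajc13 (0.17, adjusted p = 0.0538), Klhl2 (0.24, 0.055) and Mvb12a (-0.32, 0.053). With a constant floor the half-lives in WT and YBX1-/- were 2.9 and 1.97 h for Xrn1, the opposite direction, 2.69 and 4.4 h for Dnajc13, 2.28 and 2.29 h for Klhl2 and 6.07 and 5.91 h for Mvb12a. At an unadjusted p under 0.05 there were 929 genes. The count was 268 over 0 to 12 h, of which 3 were among the 8, and 0 over 0 to 6 h, where 1229 genes had an unadjusted p under 0.05; it was also 0 without the YBX1-/- 0 h library, an alternative chosen after seeing the data. Without centring, 7 genes lost label more slowly and 5 faster in YBX1-/-.

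Myc, an oncogenic transcription factor, did not pass, and Bcl2, an inhibitor of apoptosis, was not tested. Myc (ENSMUSG00000022346, chromosome 15, 61989909 to 61990374, 3' UTR) had a difference of 0.17 log2 per h (SE 0.074, adjusted p = 0.412). Its rate in WT was 43.3%, 57.3%, 23.2%, 20% and 6.2% from 0 to 6 h and 48.0%, 35.5%, 19.0%, 4.7% and 1.4% in YBX1-/-, which was lower in YBX1-/- from 0.5 to 6 h. At 12, 18 and 24 h it was 0%, 0.597% and 0% in WT and 2.16%, 1.57% and 0.98% in YBX1-/-, higher in YBX1-/- at each. Over 0 to 6 h the difference had the opposite sign, -0.26 (adjusted p = 0.448), and half-lives with a constant floor, 2.08 h (0.356 to 2.34) in WT and 0.798 h (0.551 to 0.926) in YBX1-/-, also went the other way. Bcl2 (ENSMUSG00000057329, chromosome 1, 106538178 to 106543263) had a rate above 0 in too few libraries for the test. Its rate was 35.7%, 61.3%, 22.2%, 0% and 9.4% from 0 to 6 h in WT and 26.1%, 42.4%, 19.5%, 15.6% and 2.1% in YBX1-/-.

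No gene list differed in decay rate between the genotypes over 24 h (camera, preset correlation; smallest adjusted p = 0.194, for ribosomal proteins and for myeloid maturation genes). Of 32 myeloid maturation genes 22 had a negative difference, and 0 passed over all genes but 3 when adjusted over the list alone. Of 17 genes of the m6A machinery, among them Mettl14 (0.17, SE 0.06), Ythdf3 (0.09, SE 0.035), Cbll1 (-0.15, SE 0.057) and Virma (-0.08, SE 0.069), 0 passed on either count, and of 14 Bcl2 family genes, among them Bak1 (0.20, SE 0.064), Bcl2a1a (-0.14, SE 0.058), Bcl2l13 (-0.11, SE 0.053) and Bad (0.10, SE 0.062), 0 passed on either count. Of 54 RNA decay factors 0 passed over all genes and 1 when adjusted over the list alone. For zinc finger genes, the proteasome and chromatin regulators the list median and the test differed in sign. Over 0 to 6 h, 10 lists passed with the preset correlation. Oxidative phosphorylation (adjusted p = 4.0e-07, median 0.10 log2 per h), the proteasome (0.000246, 0.13), ribosomal proteins (0.0201, 0.11) myeloid maturation (0.042, 0.08), glycolysis (0.042, 0.09) and G2/M (0.042, 0.16) lost label more slowly in YBX1-/- relative to other genes. Stem and leukaemia regulators (0.0304, -0.07), short-lived regulators (0.042, -0.06), zinc finger genes (0.0304, -0.04) and chromatin regulators (0.042, -0.08) lost it faster. With an estimated correlation none passed (adjusted p = 0.444 or more). Over 0 to 12 h, 1 list passed with the preset correlation, the short-lived regulators, in the opposite direction (adjusted p = 0.0496, median 0.10; 0.979 with an estimated correlation).

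Relative to the typical gene, myeloid maturation and G2/M transcripts held more label in YBX1-/- and ribosomal protein transcripts less, by a test with a preset correlation only. The 32 myeloid maturation genes had a median level difference of 0.19 log2 (camera adjusted p = 0.0203), with 21 higher and 11 lower. Ltf, the gene of lactoferrin in neutrophil granules, had a rate of 10.4% in WT and 23.3% in YBX1-/- at 0 h (difference 2.07, SE 0.47, higher at 8 of 8 time points). At 12, 18 and 24 h it had 0% in WT and 0.556%, 0.637% and 0.573% in YBX1-/-, so part of its difference rests on the floor. The YBX1-/- rates at 0 h given here are from the library that stood apart. At 0 h in WT and YBX1-/-, S100a9 had 18.8% and 33.6% (0.91, SE 0.25), S100a8, its partner in calprotectin, 20.3% and 36.2% (0.74, SE 0.28), and Fcnb 22.2% and 25.6% (0.61, SE 0.22), each relatively higher at 7 of 8. Of the 32, 0 passed over all genes and 1 when adjusted over the list alone. The 50 ribosomal protein genes had a median of -0.31 (adjusted p = 0.000173), with 40 lower, among them Rpl41 (-0.43, SE 0.17) and Rplp1 (-0.44, SE 0.17), while Rpl10a had 3.24 (SE 1.11). The 21 G2/M genes had a median of 0.56 (adjusted p = 0.0108), with 19 higher, among them Aurkb (2.55, SE 0.8) and Ccna2 (1.13, SE 0.53). With an estimated correlation each of the 3 lists had adjusted p = 0.789. With the 6 h time point left out, 1 list passed, as lower, and 0 as higher, so that neither myeloid maturation nor G2/M passed. Without the 0 h or the 12 h time point, or without the YBX1-/- 0 h library alone (chosen after seeing the data), 1 list passed as higher and 1 as lower. Over 0 to 6 h ribosomal proteins did not pass (adjusted p = 0.088, median -0.07), while myeloid maturation (2.38e-05) and G2/M (1.9e-05) passed as higher and stem and leukaemia regulators as lower (0.0132, -0.30); with an estimated correlation each of these 3 had adjusted p = 0.496. Without centring, where the median of all genes was -0.34, the list medians were -0.16 for myeloid maturation, which then did not pass (adjusted p = 0.426), -0.65 for ribosomal proteins and 0.21 for G2/M, which both passed; 4 lists passed in all, 1 higher and 3 lower. An exact permutation test of the list medians, chosen after seeing the data, gave unadjusted p = 0.0547 for ribosomal proteins, 0.0703 for myeloid maturation and 0.102 for G2/M (n = 8 time points). Adjusted over the 19 lists, this test gave 0.482 for each. For glycolysis and for stem and leukaemia regulators the mean differed in sign from the median and the test.

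**Figure D3:**
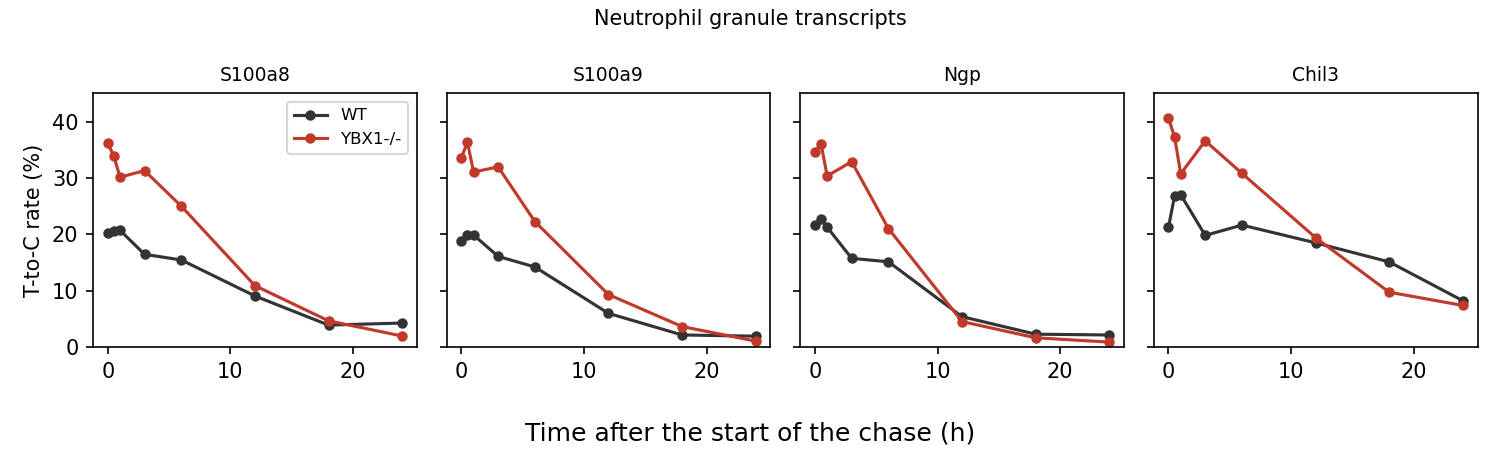
T-to-C rate in percent of 4 transcripts of neutrophil granules and neutrophil maturation, chosen after their values were seen, against hours of chase, in WT (grey) and YBX1-/- (red), 1 library per point. At 0 h S100a8 had 20.3% in WT and 36.2% in YBX1-/-, and Chil3 had 21.2% and 40.6%.

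No gene passed for the labelling level (limma; 415 genes at an unadjusted p under 0.05; smallest adjusted p = 0.779). Among genes with a mean rate above the median, those with the smallest p were all relatively higher in YBX1-/- at 8 of 8 time points: Serpine2 had 0.85 (SE 0.2), Ifitm1 0.84 (SE 0.21), S100a4 0.79 (SE 0.19), Ctla2a 2.43 (SE 0.61) and Msr1, a scavenger receptor of macrophages, 1.06 (SE 0.27). Zfp330 (-2.0, SE 0.55), Rpl36al (-0.46, SE 0.14), Minpp1 (-2.17, SE 0.65), B3glct (-3.71, SE 1.11) and Mvb12a (-3.08, SE 0.92) had the lowest p among negative differences of these genes. Dnlz (2.06) and Ltf (2.07), chosen after their values were seen, lay below this limit and had a smaller p than Serpine2 (limma, unadjusted p = 0.00102, 0.00151 and 0.0019). Erythroid, lymphoid, megakaryocyte and stromal marker lists had too few tested genes for a test.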

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

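The test of slower decay on chromosome 8 and the tests of centring and of slowly decaying transcripts were chosen after the results were seen, as was the count over the whole of chromosome 8; the other tests were written before theirs. The decay rate differed between the genotypes by the interaction test in 8 genes, which is why they are listed: Zfp330 (-0.20 log2 per h), Babam1 (-0.22), Ccdc124 (-0.20), Stambpl1 (-0.35), Gm45713 (-0.13), Nptn (0.17), Mthfd1l (0.16) and Slc7a7 (0.23). Chance could not be excluded: 5 of 100 splits that exchanged genotypes within time points gave 8 genes or more, and the highest other split gave 15. Over 0 to 12 h, 3 of 32 splits gave as many as the real 268, and the highest other gave 321.

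Of the 5 genes with faster loss in YBX1-/-, 3 lie on chromosome 8 between 70868227 and 82764228, and their WT rates stay up to 24 h. A candidate explanation is sequence variation of the WT cells in this part of the chromosome that is read as T-to-C and does not decay. Among the other genes of that stretch with a mean of at least 5 CPM, 3 of 31 held a mean rate of at least 10% at 18 and 24 h in WT with under 5% in YBX1-/-, against 18 of 5992 elsewhere (Fisher's exact p = 0.000154). Over the whole of chromosome 8, with the called genes left out, it was 14 of 334 genes, from 68904507 to 121798236, against 7 of 5689 on the other chromosomes (Fisher's exact p = 1.63e-13), and 0 genes of chromosome 8 did so in YBX1-/-. Slower decay of these transcripts in WT cannot be told apart from it: the called genes had a median change from 12 to 24 h of -0.12 log2 in WT, where the library median fell by 1.26, but they were called for WT rates that stay up, so this value does not decide. The sequence itself was not analysed here, so a variant remains a hypothesis.

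Some granule transcripts held more label in YBX1-/- relative to the typical gene, and others did not. S100a8, S100a9, Ngp and Chil3 were noticed because their rates were higher in YBX1-/-, while Ctsg and Hp were relatively higher in YBX1-/- at 1 of 8 time points, Slpi at 2, Prtn3 and Mpo at 4 and Elane at 5 (level difference -0.19 for Ctsg, -0.11 for Prtn3 and 0.02 for Elane). The rate of Mpo was uneven in WT, with 100% at 6 h and 0% at 12 h, so its count says little. Subtracting the library median may account for the direction of the difference in the lists that were not picked by these 4 genes. Without it, the median rate of a second neutrophil list (32 genes, 0 of them in the myeloid maturation list, 28 tested) was higher in YBX1-/- at 1 of 5 time points from 0 to 6 h. That of a macrophage list was higher at 0 of 5 (48.1% in WT and 37.0% in YBX1-/- at 0 h). The subtraction moves all genes of a library alike, so it cannot by itself create a difference relative to other genes. With the median subtracted, the second neutrophil list had a median level difference of 0.29, at the 99.86th percentile of 10000 lists matched on the WT slope. The list median was thus higher than that of most random lists of a similar slope, and 19 of the 28 tested genes of the list had a positive difference. Random lists treat genes as independent, so the percentile does not decide on a relative shift shared by slowly decaying transcripts. The 4 noticed genes lay at the 98.08th, which tests nothing, since they were picked for their higher rates. The 2 cultures may also differ in their share of maturing neutrophils (99.99th percentile among lists matched on mean CPM; Lcn2, 144 CPM, had 31.6% in WT and 34.8% in YBX1-/- at 0 h), or of macrophages (99.84th percentile, median 0.23, 24 of 32 genes tested; Ccl6, 1425 CPM, had 53.9% and 44.3%). The percentiles describe the label held by transcripts and not their amount, so they do not measure the share of a cell type. An effect of the genotype on these transcripts could give the same percentiles. These explanations all stay open, since there was 1 library per genotype and time point.

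Chance could not be excluded for the 3 lists with a different labelling level either: they were matched or exceeded in 11 of 100 splits, with 4 in the highest other. The real count was 0 for the level per gene (highest other 0) and for lists with a different decay rate (highest other 1); any split meets a count of 0, as 100 of 100 did for each, so the splits test neither.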

How the results depend on the processing

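Alternatives on the coverage-weighted mean, a mean of at least 5 CPM, the YBX1-/- 0 h library and chromosome 8 were chosen after seeing the data. Except where the construction shows it, the cause was not tested. The number of genes with a different decay rate, 8, was the least stable. It was 1 with a pseudocount of 0.01 or of 0.5 (Zfp330 with each), 0 without a filter and 0 without the trend of limma. With rates above 0 in all 16 libraries it was 7 (0 slower and 7 faster in YBX1-/-), and with at least 5 CPM 17 (10 slower and 7 faster). It was 268 over 0 to 12 h, 0 over 0 to 6 h and 13 with hours as a number only. Other alternatives gave 0 without the YBX1-/- 0 h library, 1 without chromosome 8, and 0 to 204 with a time point left out (204 without 12 h, 91 without 18 h). The median residual SD was 2.72 times larger over 0 to 24 h than over 0 to 6 h (0.913 against 0.336), so zeros and values near the floor at 12 to 24 h may contribute. The spread alone does not explain the count, which was 0 in the window with the smaller spread. The windows also differed in residual degrees of freedom (3 over 0 to 6 h, 4 over 0 to 12 h, 6 over 0 to 24 h), so the ratio does not decide. Babam1 turned to 0.033 over 0 to 6 h, Myc to -0.26, and Ybx1 from -0.04 to 0.035 over 0 to 12 h and 0.042 over 0 to 6 h.

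The library level difference stayed negative in all 17 alternatives (-0.51 to -0.24). It missed the threshold at -0.41 without a filter, -0.51 over 0 to 6 h (5 pairs allow no p under 0.0625), -0.33 with the library mean, and with 5 of the 8 time points left out in turn (-0.35 to -0.24; over all 8, -0.42 to -0.24). The difference of library slopes reversed to -0.00496 over 0 to 12 h and -0.095 over 0 to 6 h, and passed at 0.029 with the library mean. Half-lives of the library medians were 3.88 h in WT and 4.21 h in YBX1-/- by the straight line and 2.76 and 2.66 h with a constant floor. The order of the genotypes also turned with a constant floor for Stambpl1 (1.84 h in WT and 2.31 h in YBX1-/-), Xrn1 (2.9 and 1.97 h), Myc (2.08 and 0.798 h), Zfp330 (1.66 and 1.74 h), Babam1 (4.61 and 4.62 h) and Ccdc124 (3.95 and 4.15 h). For the library medians and for each of these genes, the ranges with each time point left out overlapped between the genotypes. The fits with a floor therefore do not settle which genotype lost label faster.

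With rates above 0 in all 16 libraries, 2805 genes lost label in WT and 2805 in YBX1-/-, as fewer genes were tested. Genes with a different level were 2 without a filter. Lists with a different decay rate were 3 with rates above 0 in all libraries, 1 over 0 to 12 h, 10 over 0 to 6 h (short-lived regulators turned from slower over 0 to 12 h to faster over 0 to 6 h), 1 with at least 5 CPM, 1 without the YBX1-/- 0 h library, and 0 to 1 with a time point left out. Lists in WT decay were 12 without a filter, 3 with rates above 0 in all libraries, 0 with an estimated correlation, and 3 to 6 with a time point left out. Lists with a different level were 3 over 0 to 6 h, with stem and leukaemia regulators in place of ribosomal proteins, 2 (1 higher, 1 lower) without a filter, with rates above 0 in all libraries, with the coverage-weighted mean or without the YBX1-/- 0 h library, 0 with an estimated correlation and 1 to 3 with a time point left out: 1, lower in YBX1-/-, without 6 h, which ended the calls of myeloid maturation and G2/M, and 2 without 0 h or without 12 h.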

Other observations

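Some transcripts still had a rate of at least 10% late in the chase in both genotypes, which does not mean that their rate was unchanged. Without an unlabelled library, background T-to-C changes are not excluded for them. Of 6027 genes with a mean of at least 5 CPM, 17 had a mean rate of at least 10% at 18 and 24 h in both, among them Lxn (20.4% in WT and 21.4% in YBX1-/-), Sharpin (22.3% and 14.6%), Borcs8 (38.7% and 39.5%) and Lyz1 (24.9% and 26.4%). With at least 10% in 1 genotype and under 5% in the other, there were 24 genes in WT and 16 in YBX1-/-, among the latter Ctla2a (10.6% against 0.333%) and Tlr7 (25% against 4.01%). These genes were chosen after their values were seen.

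Basophil, eosinophil and mast cell genes, a list written after the pattern of granule genes was seen, had 3 of 11 members tested, at the 37.13th percentile of lists matched on mean CPM.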
